A study of Mus musculus with 2 samples.

How the data were processed

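Messenger RNA was sequenced from YTN16, a mouse gastric cancer cell line, after introduction of a short hairpin RNA (shRNA). One culture carried a control hairpin (shControl) and the other a hairpin against Gas6 (shGas6), with 1 library each. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded poly(A) kit. Per the submitters' processing notes, Trimmomatic, a read trimmer, was used and the genome build was GRCm38 (mm10). The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here.

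The deposited table holds 45777 genes under NCBI gene identifiers. Per the file headers, the authors gave each gene a raw read count, an FPKM value and a TPM value in each library. The deposited counts are whole numbers that sum to 50756676 in shControl and 51807140 in shGas6, and they were the basis of every result. The deposited TPM values, which the authors scaled to a fixed library total, and the deposited FPKM values, scaled by the authors to transcript length and library size, served only as alternatives. Whether a count stands for a read or a read pair is not stated. Without a known strand setting, reads of a gene and of an antisense partner could not be told apart. Near-identical family members (for example of the H2, Oas, Gbp and Ifit3 families, or Muc3 and Muc3a) may share reads, so the split of counts within such families is uncertain.

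The 2 columns were assigned to the 2 samples by their names and titles. With 1 library per group, no spread between replicates could be estimated. The differences have no replicate check, no test across conditions was possible, and no p-value is given. Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3). The log2 ratio of a gene is log2 of the scaled count plus a pseudocount of 0.5 in shGas6 minus the same in shControl. Ratios printed as folds are of scaled counts without the pseudocount. Each carries an exact (Clopper-Pearson) 95% interval from the binomial split of the gene's counts (scipy 1.17.1). These intervals are meant for counting error only, and they say nothing about variation between cultures. Reads copied by PCR are not independent molecules, so the intervals may be too narrow even for counting error. Where a gene had 0 counts in 1 library, the fold was computed against a floor of 3 counts in that library and is a lower bound. That floor corresponds to 0.0590 CPM (the count scaled by the TMM-adjusted library total) in shControl and 0.0580 CPM in shGas6.

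A gene was called measured at 1 CPM or more in at least 1 library, which left 13367 genes, with a median of 1506 counts in shControl and 1577 in shGas6. A gene was counted as higher or lower by size alone, at a fold of 2 or more. Sets of genes were described by 42 lists fixed before the data were examined. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these 2 libraries only. The 3 lists with a member at 0 in 1 library had the same median with that member at its lower bound.

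The genes named in the text followed a rule fixed before the data were examined. It took 12 genes in any case (Gas6, Axl, Mertk, Tyro3, Pros1, Cd274, H2-K1, H2-D1, B2m, Trp53, Cdh1 and Vim). It added, in each direction, the 12 genes with the largest log2 ratio at 10 CPM or more in the higher library, without predicted genes, microRNAs, small nucleolar RNAs and pseudogene symbols. It also allowed up to 4 members with the largest absolute log2 ratio from each list. Genes named outside this rule are marked as such, and some genes that the rule takes are not reported here. Coordinates are from the NCBI annotation of GRCm38.p6, matched by gene identifier (45675 of 45777 genes).

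The procedure was tested on simulated data. Poisson counts were drawn from the mean of the real libraries, with 200 of 13049 measured genes changed by 3-fold or 4-fold. At each fold size and in each direction, 100% of the 50 simulated genes passed the 2-fold mark. The intervals held the true fold for 90% to 98% of these genes, depending on the fold and direction, and for 95.2% of the unchanged genes. Poisson counts meet the assumption behind the intervals, so this coverage says nothing about other sources of error. The simulation also changed fewer genes than differed in the data, in equal numbers in both directions. It therefore did not test the scaling under changes as many and as unequal as those observed. Alternatives were other scalings (total count, DESeq2 1.42.0 size factors, upper quartile), a pseudocount of 5, filters of 1 count and of 5 CPM, thresholds of 1.5-fold and 4-fold, the counting interval in place of the point estimate, and the deposited TPM and FPKM values with a pseudocount of 0.1. Corrections for GC content with transcript length and for chromosomal position (the median of the 50 surrounding measured genes) were chosen after the data were seen (lowess from statsmodels 0.14.6).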

Results

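The data comprised 2 poly(A) RNA libraries of the mouse gastric cancer line YTN16, 1 with a control hairpin (shControl) and 1 with a hairpin against Gas6 (shGas6). GAS6 is a secreted ligand of the TAM receptor tyrosine kinases AXL, MERTK and TYRO3. The series was set up around the GAS6/AXL pathway in the response to immunotherapy, and the design gives 1 comparison, knockdown against control hairpin. The libraries held 50756676 and 51807140 counts, with 20327 and 20649 genes detected. The most abundant gene in both, named after its values were seen, was Eef1a1, at 0.810% and 0.745% of the counts, and the 10 most abundant genes took 4.33% and 3.78%. There was 1 library per group, so every value below is a difference between 2 libraries without a replicate check, and intervals in brackets are 95% intervals for counting error only.

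Gas6 transcripts were lower in the shGas6 library, at 29.0% of the control level (interval 26.6% to 31.5%). Gas6 (NCBI gene 14456, chromosome 8, 13465374 to 13494535) had 2480 counts in shControl and 731 in shGas6, or 48.8 and 14.1 CPM, a fold of 3.45 (3.18 to 3.75). Its receptor Axl was abundant in both libraries, at 599 and 449 CPM, 1.33-fold lower in shGas6 (1.31 to 1.36). Tyro3 was at 13.1 and 14.6 CPM, 1.11-fold higher (1.00 to 1.24). Mertk had 0 counts in both libraries, which allows up to 0.0590 CPM. Pros1, the other TAM ligand, was 1.19-fold lower (1.14 to 1.25). Of the 9 measured genes of the GAS6 and TAM receptor list, Gas6 was the 1 gene past 2-fold. The list median log2 ratio was -0.26, at percentile 5.78 of matched random lists. The measured genes of chromosome 8 as a whole had a median log2 ratio of -0.17.

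The difference between the libraries extended well beyond Gas6. Of 13367 measured genes, 1155 were at least 2-fold higher in shGas6 and 828 at least 2-fold lower, together 14.8%. Within 1.5-fold lay 9543 genes (71.4%). At 4-fold or more, 422 genes were higher and 342 lower, and at 16-fold or more 96 were higher and 108 lower. For 876 of the higher and 596 of the lower genes the whole counting interval lay beyond 2-fold. These counts rest on a size threshold and not on a test.

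**Figure D1:**
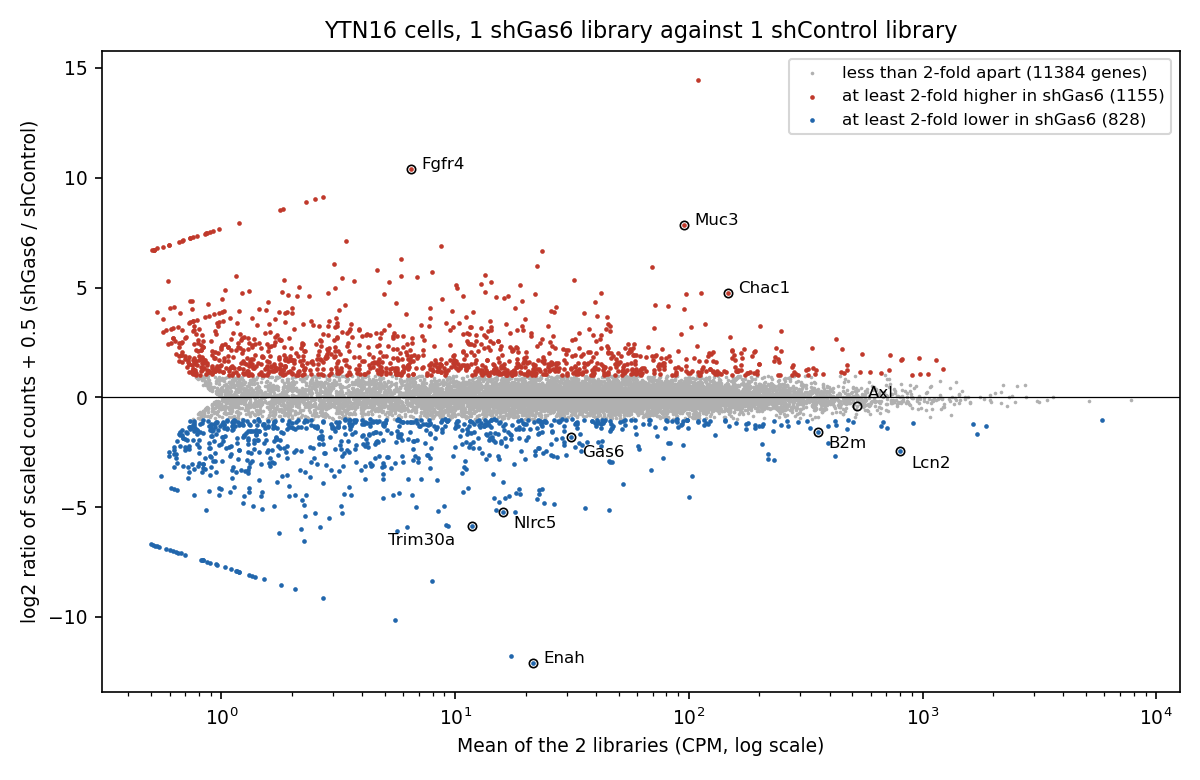
Log2 ratio (vertical axis, shGas6 over shControl) against mean level (horizontal axis, CPM on a log scale) for the 13367 measured genes, each point 1 gene in 1 library per group. The 1155 higher genes are red, the 828 lower genes blue, and the oblique rows of points are genes with 0 counts in 1 library, whose ratio depends on the pseudocount of 0.5.

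The genes with the largest higher levels in shGas6 included receptors and surface proteins of epithelia. Fgfr4, a fibroblast growth factor receptor (chromosome 13, 55152818 to 55168759), had 0 counts in shControl and 672 in shGas6, at least 220-fold higher. The mucin gene Muc3 was at 0.806 CPM in shControl and 189.96 CPM in shGas6, 236-fold higher (174 to 328). Muc3a, which lies beside it and may share its reads, was 48.7-fold higher (27.6 to 94.7). Upk1b, a uroplakin of the urothelium, was 84.0-fold higher (40.5 to 210), and Ly6d, a surface protein of stratified epithelia, 38.1-fold (27.5 to 54.4). Perp, a desmosomal protein and p53 target, was 40.6-fold higher (32.5 to 51.4). Nbl1, a secreted antagonist of bone morphogenetic proteins, was 103-fold higher (68.8 to 164). Col14a1, a collagen, was 64.2-fold higher (46.0 to 92.4). Flrt2, Elmod1 and B4galt4 were between 45.6-fold and 53.1-fold higher.

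The genes with the largest lower levels included an actin regulator and a Hedgehog pathway component. Enah, the actin regulator (chromosome 1, 181896384 to 182027556), had 2193 counts in shControl and 0 in shGas6, at least 744-fold lower. Smo, the Hedgehog signal transducer, had 810 counts and 2, a ratio of 412 (114 to 3408). Tgfbr3, a TGF-beta co-receptor, was 63.7-fold lower (34.4 to 133). Trim30a and Nlrc5, both interferon-inducible, were 59.8-fold (38.5 to 98.2) and 37.5-fold lower (27.7 to 52). Nlrc5 is the transactivator of MHC class I genes (chromosome 8, 94434335 to 94527272) and was at 31.2 CPM in shControl and 0.831 CPM in shGas6. Dmrta2, Gng2, Lipn, Mcub, Akr1c18 and Pon3 were between 35.9-fold and 71.7-fold lower.

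MHC class I presentation and interferon-response genes were lower in shGas6 as groups. Of 22 measured MHC class I presentation genes, 8 were at least 2-fold lower, none was at least 2-fold higher, and 19 had a ratio below 0. The list median log2 ratio was -0.77, below all of the 10000 random lists. B2m, the shared light chain of MHC class I, was at 531 and 179 CPM, 2.96-fold lower (2.89 to 3.03). The immunoproteasome subunit Psmb9 was 3.42-fold lower (2.57 to 4.61) and the non-classical gene H2-Q4 2.44-fold lower (2.24 to 2.67). The classical heavy chains stayed within 2-fold, with H2-K1 1.89-fold lower (1.85 to 1.93) and H2-D1 1.56-fold lower (1.53 to 1.59).

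Of 38 measured type I interferon response genes, 13 were at least 2-fold lower and none at least 2-fold higher. Their median log2 ratio was -0.72, again below all random lists. Besides Trim30a, the antiviral oligoadenylate synthetase Oas1a was 4.51-fold lower (4.28 to 4.75), Oas1g 3.93-fold (3.65 to 4.23) and Rsad2 (viperin) 4.26-fold (2.78 to 6.74). Of 21 interferon gamma response genes, 8 were at least 2-fold lower and none at least 2-fold higher, with a median of -0.43 (percentile 0.07). Of these 8, all but Igtp (named after its values were seen) were guanylate-binding proteins, and 5 of the 21 ratios were above 0. Guanylate-binding proteins, a family whose members may share reads, led this list, with Gbp2 7.74-fold lower (6.14 to 9.87), Gbp6 7.06-fold (6.08 to 8.24), Gbp7 6.57-fold (5.10 to 8.58) and Gbp9 4.77-fold (4.36 to 5.22). Cd274, which encodes PD-L1 and belongs to this list, was low in both libraries, at 2.81 and 2.61 CPM, with a fold whose counting interval included 1 (1.08-fold lower, 0.846 to 1.37). Leukocyte transcripts were scarce, with 5 of 21 markers measured. Ptprc, Lyz2 and Fcer1g were below 1 CPM in both libraries, and Tyrobp had 0 counts in both (genes chosen after their values were seen). Laptm5 was at 0.157 CPM in shControl and 1.37 CPM in shGas6, and Coro1a at 2.30 and 2.01 CPM. S100a8, a neutrophil protein of the same list, was at 20.5 CPM in shControl and 1.02 CPM in shGas6, and its partner S100a9 at 1.73 and 1.47 CPM.

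**Figure D2:**
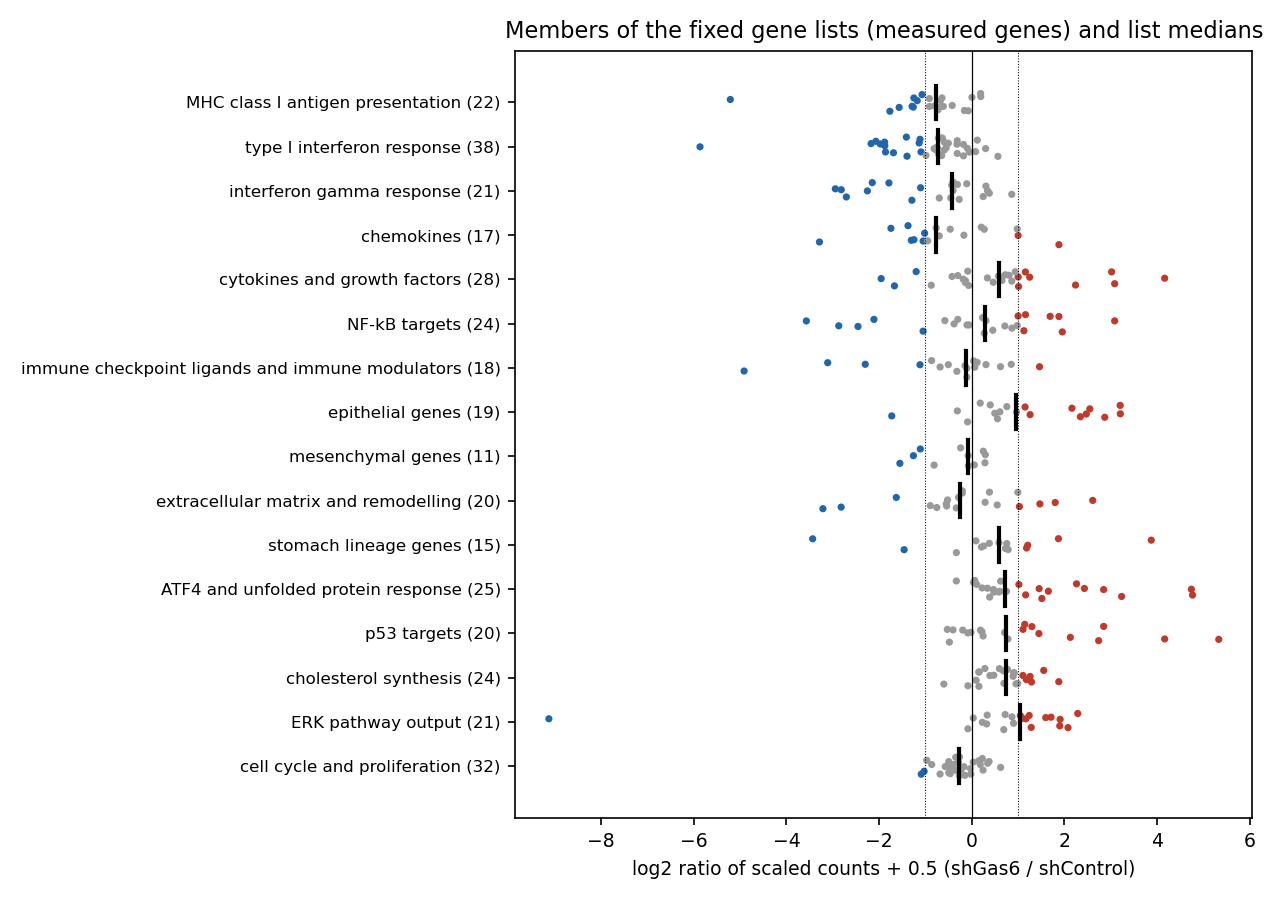
Log2 ratio (horizontal axis, shGas6 over shControl) of each measured member of 16 fixed lists, with the number of members in brackets, black bars for list medians, dotted lines at 2-fold and random vertical jitter. The MHC class I and type I interferon lists have medians of -0.77 and -0.72 and no member past 2-fold higher, and the ATF4 list has a median of 0.72 and no member past 2-fold lower.

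Among secreted factors, the chemokine list was lower and the joint list of cytokines and growth factors higher by median. Of 17 measured chemokines, 7 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -0.77, below all random lists. Ccl5, a T-cell attractant, was 3.36-fold lower (2.66 to 4.28), Pf4 9.92-fold lower (6.71 to 15.2), and the neutrophil attractant Cxcl3, at 1017 and 392.2 CPM, 2.59-fold lower (2.55 to 2.64). Ccl20, a ligand of CCR6, was 3.69-fold higher (3.56 to 3.82). Of 28 cytokines and growth factors, 8 were at least 2-fold higher and 3 lower, with a median of 0.59, above all random lists. The higher ones included the stress cytokine Gdf15 (18.0-fold, 16.3 to 19.8), Tnf (8.51-fold, 7.34 to 9.92), the EGF receptor ligand Areg (8.12-fold, 7.80 to 8.44) and Vegfa (4.73-fold, 4.57 to 4.89).

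NF-kB targets, which share 5 members with the chemokines, were split, with 7 of 24 at least 2-fold higher and 5 lower, and a median of 0.29 (percentile 99.87). Vcam1, an adhesion molecule for leukocytes, was 11.9-fold lower (11.1 to 12.8), complement C3 7.31-fold lower (7.03 to 7.61) and the iron-binding lipocalin Lcn2 5.48-fold lower (5.38 to 5.59), whereas Tnf was higher. Among 18 measured immune checkpoint ligands and modulators, 4 were at least 2-fold lower and 1 higher, and the median of -0.13 lay within the random lists (percentile 20.1). Vtcn1 (B7-H4) was 32.3-fold lower (15.4 to 81.2), Tnfrsf14 8.86-fold lower (5.35 to 15.6) and Tnfsf10 (TRAIL) 5.09-fold lower (2.71 to 10.4), each under 5 CPM. Pvr, the ligand of TIGIT and CD226, was at 40.3 and 111 CPM, 2.76-fold higher (2.62 to 2.90).

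Epithelial genes were higher in shGas6 as a group, while the median of the mesenchymal genes lay within the random lists. Of 19 measured epithelial genes, 9 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.97, above all random lists. With every gene of at least 1 count included, the epithelial median was 0.61, again above all of its random lists. The desmosomal plaque protein Dsp was at 19.9 and 184 CPM, 9.23-fold higher (8.65 to 9.85). Krt7 was 9.28-fold higher (7.66 to 11.3), the desmosomal Pkp3 7.42-fold (5.15 to 11) and the protease inhibitor Spint1 5.86-fold (5.37 to 6.40). E-cadherin (Cdh1) was at 112 and 218 CPM, 1.95-fold higher (1.89 to 2.02). Of 6 measured claudins, 4 were at least 2-fold higher and none lower (median 1.30, percentile 99.99), led by Cldn15 (5.12-fold) and Cldn3 (5.09-fold). Under the same inclusion, the claudin median was 0.28 and lay within the random lists (percentile 86.3). The median of 18 keratins, 5 of them also in the epithelial list, was 0.54 (percentile 99.8), with 7 higher and 2 lower, and 0.91 under that inclusion. Krt7, Krt79 and Krt83 lie on chromosome 15, whose measured genes had a median of 0.26.

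Among 11 measured mesenchymal genes, 3 were at least 2-fold lower and none higher, and the median of -0.08 was at percentile 32.8. S100a4 was 2.93-fold lower (2.85 to 3.02), fibronectin (Fn1) 2.39-fold (2.34 to 2.44) and Sparc 2.16-fold (1.91 to 2.44), while vimentin (Vim) was at 1884 and 1792 CPM, 1.05-fold lower (1.04 to 1.06). Extracellular matrix and remodelling genes differed in both directions, with 4 of 20 higher, 3 lower and a median of -0.24 (percentile 2.97). That median was -0.43 without a filter beyond 1 count and -0.33 at 5 CPM, both outside the central 95% of random lists. The collagenase Mmp13 was at 380.1 and 53.9 CPM, 7.06-fold lower (6.78 to 7.35). The stomach lineage list, which also holds intestinal genes, had a median of 0.59 (percentile 99.9), with 4 of 15 higher and 2 lower. After the median of the 50 surrounding genes was subtracted from each gene, the stomach median was 0.33. The transcription factor Gata5 was 14.8-fold higher (11.7 to 18.9), and the trefoil peptide Tff2 10.9-fold lower (8.78 to 13.6).

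The ATF4 and p53 target lists were higher in shGas6 as groups, with under 50% of the members of each past 2-fold. Of 25 genes of the ATF4 and unfolded protein response list, 11 were at least 2-fold higher, none was lower by that much, and 24 had a ratio above 0, with a median of 0.72, above all random lists. The glutathione-degrading enzyme Chac1 was at 10.4 and 283 CPM, 27.3-fold higher (25 to 29.8), and the pseudokinase Trib3 at 8.08 and 217 CPM, 26.8-fold higher (24.3 to 29.6). Atf3 was 9.42-fold higher (8.99 to 9.88) and Sesn2 7.21-fold (6.57 to 7.91). Among 20 p53 targets, 9 were higher and none lower by 2-fold, with a median of 0.75, above all random lists. The list was less uniform, with 14 ratios above 0 and 6 below. Besides Perp and Gdf15, the cell cycle inhibitor Cdkn1a was 6.70-fold higher (5.72 to 7.88). Trp53 itself was at 13.2 and 15.6 CPM, 1.19-fold higher (1.07 to 1.32). Sesn2 belongs to both lists.

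Genes of sterol synthesis and of ERK pathway output were also higher. Of 24 cholesterol synthesis genes, 6 were at least 2-fold higher and 22 had a ratio above 0, with a median of 0.73, above all random lists. Insig1, a feedback regulator of the pathway, was 2.94-fold higher (2.74 to 3.16) and the epoxidase Sqle 2.45-fold (2.35 to 2.54). Of 21 ERK output genes, 11 were at least 2-fold higher and 1 lower, with a median of 1.05, above all random lists. The feedback inhibitor Spry4 was 4.89-fold higher (4.33 to 5.54), Egr1 4.23-fold (4.08 to 4.38) and Fos 3.76-fold (3.53 to 4.0), whereas Etv1 had 277 counts in shControl and 0 in shGas6, at least 93.9-fold lower.

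Medians of other signalling lists were smaller. YAP and TEAD targets had a median of 0.29 (percentile 98.6), with 4 of 15 higher and none lower, led by F3 (3.32-fold, 3.22 to 3.42). TGF-beta targets had a median of 0.29 (percentile 99.0), with 5 of 15 higher and 1 lower. Without an expression filter beyond 1 count, both lay within the random range, at percentiles 95.55 and 97.2. Hypoxia and glycolysis genes had a median of 0.18 (percentile 98.7), with 1 of 24 higher, Ndrg1 (6.27-fold), and 2 lower, among them Car9 (8.20-fold lower, 7.07 to 9.55). Cell cycle genes had a median of -0.28 (percentile 0.01), with 2 of 32 at least 2-fold lower, Plk1 (2.13-fold, 2.05 to 2.21) and Ccne2 (2.04-fold, 1.83 to 2.28), and none higher. Apoptosis regulators had a median of 0.00 (percentile 58.0), with 1 of 24 higher and 2 lower. Of the 39 lists with at least 3 measured genes, 6 medians lay below and 14 above the central 95% of their random lists, where 1.95 in all would be expected of independent random lists.

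The log2 ratios also differed between chromosomes. The median was -0.32 over 782 measured genes of chromosome 1, -0.28 over 513 genes of chromosome 13, -0.18 over 876 genes of chromosome 5 and -0.17 over 733 genes of chromosome 8. It was 0.26 over 533 genes of chromosome 15 and 0.16 over 342 genes of chromosome 18. These 6 chromosomes were those with a median at least 0.15 from 0, and their medians lay outside the range of 2000 random gene sets of the same size. The smaller medians of chromosomes 11 (0.06), 16 (0.10) and X (-0.11) also lay outside that range. On chromosome 1, 34 genes were at least 2-fold higher and 95 lower, and on chromosome 15, 80 were higher and 20 lower.

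**Figure D3:**
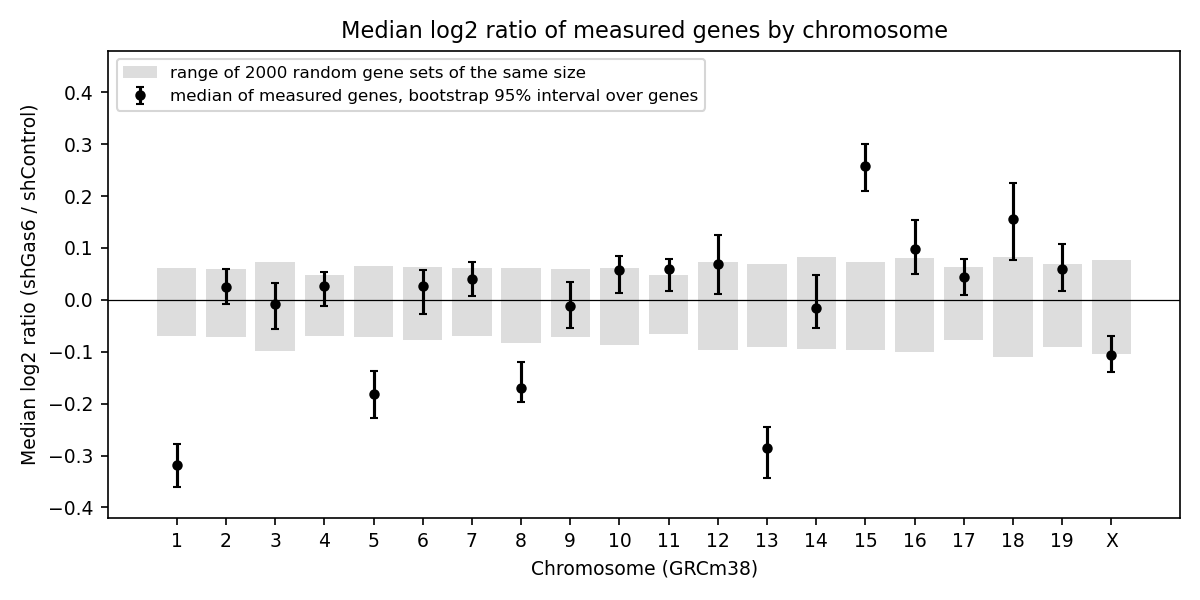
Median log2 ratio (vertical axis, shGas6 over shControl) of the measured genes of each chromosome (horizontal axis), with bootstrap 95% intervals over genes as bars and the range of 2000 random gene sets of the same size in grey. Chromosomes 1 and 13 sit at -0.32 and -0.28 and chromosome 15 at 0.26, outside the grey ranges.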

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

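The settings below were planned before the data were examined, except the corrections for position and for GC content with transcript length. The numbers of genes at least 2-fold higher and lower in shGas6 (1155 and 828) stayed within 1.5 times under 3 other scalings, a pseudocount of 5, the deposited TPM and FPKM values, the counting interval beyond 2-fold, and both corrections, with ranges of 876 to 1210 and 596 to 864. The GC and length correction was made on 11864 genes. They moved further, by construction, with the filter and the threshold. Without a filter beyond 1 count they were 4202 and 3339, at 5 CPM 729 and 466, at 1.5-fold 2145 and 1679, and at 4-fold 422 and 342. The log2 ratio of Gas6 (-1.79) ranged from -1.83 to -1.73 over 6 settings. Of 1026 values of 171 other named genes, 916 lay within the gene's counting interval, 108 moved further and 2 reversed. The reversed values were of the H2-DMa log2 ratio, at -0.0062 with the deposited TPM and -0.0436 with the deposited FPKM, and the cause was not tested. Of 309 list medians, 297 moved by less than the SD of matched random lists and 12 by more, and no median that lay outside the central 95% of random lists in the main setting reversed. The endothelial median (-0.24) was 1.18 at 5 CPM. At 5 CPM the MHC class II, leukocyte and imprinted lists were left with too few genes for a median. Medians of the apoptosis, integrin, NRF2, protocadherin, S100 and endothelial lists changed sign in at least 1 planned setting, and those of the metalloproteinase, semaphorin and WNT lists, besides the apoptosis, integrin and S100 lists, with a correction. Without a filter the YAP, TGF-beta and claudin medians lay inside the random range, and the matrix, collagen and aldo-keto reductase medians outside it. At 5 CPM the matrix, serpin and endothelial medians lay outside it, and the imprinted median did so under the 3 other scalings and with a pseudocount of 5. Of 468 counts of list members past 2-fold, 447 stayed within 1.5 times and 21 did not. The median over all measured genes moved by less than 0.1 under every scaling. No paired analysis was possible because each group has 1 library, and for the same reason no replicate was left out.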

Other observations

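The tests of leukocytes and of Nlrc5, the choice of the chromosome pattern and the values of on-off genes below came after the values they rest on had been seen. Among gene families that the comparisons above do not cover, the histone and ribosomal protein genes had medians outside the central 95% of random lists. Of 21 measured histone genes, 10 were at least 2-fold higher in shGas6 and none lower, with a median log2 ratio of 0.92 (percentile 99.9). Linker histones were among them, with H1f3 7.32-fold higher (5.46 to 10.0) and H1f2 at 29.1 and 102 CPM (3.52-fold, 3.32 to 3.73), although both lie on chromosome 13, whose median was -0.28. Poly(A) libraries count only the polyadenylated part of histone transcripts. Ribosomal protein genes had a median of -0.19 (percentile 0.03), with 72 of 81 below 0 and 1 past 2-fold. That 1 member (Rps3a3) and 3 others are annotated as pseudogenes, and the median without them was -0.18. The random lists matched to them had a median of -0.05, and the GC and length correction moved the ribosomal median to -0.12. The hemidesmosomal integrin Itgb4 was 12.7-fold higher (11.4 to 14.3), while the 16 integrins as a list had a median of -0.02 (percentile 47.6), with 3 higher and none lower.

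Enzymes of detoxification were uneven. Of 26 aldo-keto reductases and glutathione transferases, 6 were at least 2-fold lower and 2 higher, with a median of -0.21 (percentile 2.68), and Akr1b8 was at 479 and 183 CPM (2.62-fold lower, 2.56 to 2.68). NRF2 and oxidative stress genes, which share 8 members with that family, had 3 of 23 lower, none higher and a median of 0.03 (percentile 71.4). Collagens (15 measured, 3 higher, 1 lower), serpins (15, 2 higher, 5 lower) and matrix metalloproteinases (9, 3 higher, 3 lower) had medians of -0.34, -0.30 and -0.31, at percentiles 3.77, 3.49 and 6.97. The serpin median was -0.67 (percentile 0.05) at 5 CPM and -0.01 after the median of surrounding genes was subtracted. The metalloproteinase median was -0.04 at 5 CPM and 0.06 after that subtraction. S100 proteins (11 measured, 1 higher, 2 lower), protocadherins (5, 0 higher, 2 lower), semaphorins and plexins (22, 3 higher, 4 lower) and WNT targets with stem cell genes (11, 1 higher, 3 lower) had medians between -0.04 and 0.08, at percentiles 49.5, 48, 75.1 and 70.3. After the subtraction of surrounding genes, the S100 and protocadherin medians were -0.37 and -0.21. The 3 measured MHC class II genes had a median of 1.06 (percentile 85.6), with Cd74 2.77-fold higher (1.76 to 4.47) and H2-DMa 2.09-fold higher by counts but not by the deposited TPM or FPKM, with which the list median was 0.25 and 0.19. The 3 measured imprinted genes had a median of 0.95 (percentile 97.4), with 1 higher and none lower. Among markers of other cell types, 5 leukocyte genes (1 higher, 1 lower) had a median of -0.19 (percentile 30.5) and 4 endothelial genes (2 higher, 2 lower) a median of -0.24 (percentile 27.4), which was 1.18 at the 5 CPM filter. Of the fibroblast markers 1 was measured (Col1a1, 1.22-fold higher, 0.840 to 1.79), and of the erythroid markers 0. The 2 mitochondrially encoded genes in the table were within 2-fold, mt-Rnr2 at 322 and 456 CPM and mt-Rnr1 at 211 and 161 CPM.

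A set of 10 genes had 3 counts or fewer in 1 library and 5 CPM or more in the other, 5 in each direction, of which 8 were at exactly 0. Besides Fgfr4, Enah, Smo and Etv1, they included Coro2b, Shc2, Fgf21, the pseudogene Gm20056 and the long non-coding RNA Gm15564, which had 0 counts in shControl and 11326 in shGas6 (genes named here after their values were seen). These genes were at first a pattern to be weighed, with predictions for overlapping genes and for lost or gained segments. Both outcomes were seen before the chromosomes were weighed in their place, so they are given as values. None of the 10 genes had an overlapping annotated gene that gained as much as 50% of the missing reads, and the median log2 ratio of 17 flanking measured genes, taken in the direction of the on-off gene, was 0.14 (bootstrap interval -0.23 to 0.30).

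The first pattern is the number of genes at least 2-fold apart, 1983 in all. Counting noise gave 0 such genes in a simulation with equal expression. That simulation drew Poisson counts only and held no variation from library preparation or handling, which was not tested. Subtracting the trend on GC content and transcript length, known for 85.9% of these genes, left 98.8% of their number. Subtracting the median of the 50 surrounding measured genes left 96.2%. These values argue against GC and length bias, and against shifts of long segments, as the main source. A gain or loss that spans only a few genes hardly moves a median of 50 neighbours, so short segments were not tested. The knockdown itself, an effect of the hairpin on other transcripts, and divergence or a different growth state of the 2 cultures may each account for the remainder, and 1 library per group leaves them open.

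The second pattern is the shift of chromosomes 1, 5, 8, 13, 15 and 18. GC and length bias is an unlikely source, since the smallest of the 6 medians, in its own direction, was 0.18 after that correction. Without genes at least 2-fold apart, the smallest median was 0.12 (bootstrap interval 0.07 to 0.20, chromosome 18). Genes with smaller differences were thus shifted as well. A few strongly changed genes barely move a median, so these values argue against them as the source of the shift. The argument is weakest on chromosome 18. Dropping as many genes from the shift's own side alone would have left 0.05 on chromosome 18. On the others it would have left between 0.07 (chromosome 5) and 0.21 (chromosome 1). A difference in copy number between the 2 cell populations is a candidate explanation. The median kept its direction and at least 50% of its size at low, middle and high expression on 4 of the 6 chromosomes (for chromosome 13, -0.28, -0.30 and -0.28), but not on chromosomes 8 and 18, so the question stays open without DNA data.

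The third pattern is the lower level of the type I interferon response and MHC class I lists, without the interferon gamma list. After the GC and length correction the median of their 59 members was -0.74 (bootstrap interval -0.92 to -0.65). For leukocytes in the control culture, 0 of 6 transcripts of such cells were above 5 CPM and 2-fold higher there. That rule was set after their counts had been seen, so its outcome was fixed and it cannot decide the question. The values show only that these 6 were scarce in shControl, with Coro1a the highest at 2.30 CPM. S100a8, of the leukocyte list but not of these 6, did pass both marks (20.5 CPM, with S100a9 at 1.73 CPM). How far the lower Nlrc5 accounts for it stays open, since the 38 type I interferon genes, none of them in the MHC class I list, had the median that defines the pattern (-0.72, -0.99 to -0.59). A lower interferon tone in the shGas6 culture, or a response to the control hairpin itself, may underlie it, and neither could be tested with these libraries.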
